A study of Mus musculus with 3 samples.

How the data were processed

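Single-cell RNA sequencing was used to profile 3 libraries of mouse cells at 2 times during the direct conversion of embryonic fibroblasts toward motor neurons. Per the labels, the cells carried the Hb9::GFP reporter, a green fluorescent protein driven by regulatory sequence of the motor neuron gene Mnx1 (also called Hb9). They had received a cassette of Lhx3, Neurog2 and Isl1, called LNI, together with DDRR, which joins an activated HRAS mutant to p53DD, a fragment of p53 that blocks the normal protein. Of the libraries, 2 were made at 14 dpi (the time unit of the labels) from cells sorted as Hb9::GFP-positive, 1 from a culture with supplements and 1 from a culture without them. The supplements were the growth factors BDNF, CNTF, GDNF and FGF with RepSox, an inhibitor of the kinase of a TGF-beta receptor. The third library was made at 4 dpi, with supplements, from cells sorted for low CellTrace signal, a dye that each division dilutes. Each group holds 1 library, and all 3 carry the same batch date in the labels.

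Per the labels' protocols, cells at 4 dpi were dissociated with trypsin and cells at 14 dpi with papain and DNase, live cells were sorted, and libraries were prepared with the 10x Genomics 3′ v3.1 chemistry. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, written by Cell Ranger 6.1.1, per the file headers. The genome build was GRCm39, per the submitters' processing notes. The deposited feature table holds 31783 features, of which the last is an added EGFP sequence, named v.EGFP, which reads the reporter. Features with the same symbol were summed, which left 31744 symbols. How barcodes were called as cells, and whether reads in introns were counted, is not given in the sources used here. Reads of the 3′ chemistry do not separate transcripts of the introduced Lhx3, Neurog2, Isl1, HRAS and p53 sequences from those of the cell's own genes.

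The deposited matrices held 2467 barcodes with supplements at 14 dpi, 3893 without supplements and 4602 at 4 dpi. Barcodes with at least 500 genes and at most 20% of UMIs from the 13 mitochondrially encoded genes were kept, which left 2314, 3716 and 4492 cells and removed 153, 177 and 110. Scrublet (in scanpy 1.11.5) was run per library on the kept cells and called 3, 1 and 1 doublets. That is too few for a caller that has worked, so doublets were kept in the main values and the 5% of cells with the highest scores were left out as an alternative.

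Kept cells of all 3 libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden clustering at resolution 1 gave 15 clusters. Clusters were named from marker genes fixed before the data were examined, 18 for neuron-like and 20 for fibroblast-like cells among 13 classes. The score is the mean log2 of CPM plus 10 over neuron markers minus the same mean over fibroblast markers. A cluster was called neuron-like at a score of at least 2 with at least 15 neuron markers at 20 CPM or more, and fibroblast-like at a score of -2 or lower with at least 15 fibroblast markers at that level. Other classes needed 3 markers at that level and a mean of at least 1.5. A cluster stayed unnamed where another class had more markers among its top 10 genes. It also stayed unnamed where its cells were far shallower than their library (cluster 6) and no marker of the class stood in the top 10. These thresholds were set after the data were seen. They replaced a rule tried first, which asked for a mean log2 fold of at least 0.8 of a class's markers against all other cells. That rule named clusters 2 and 7 neuron-like and left out cluster 9. It was replaced after its shares were seen, because its classes changed with the clustering resolution. The thresholds of the second rule were chosen with the numbers of cells they gave at each resolution in view, before genes were compared, and its shares change with the resolution too. No threshold other than these was run. Shares under both rules are given.

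With 1 library per group there is no test between groups, and no p-value is given. UMIs were summed per library over the cells compared and expressed as CPM, the count per 1e6 UMIs of that sum. Libraries were compared as log2 ratios with an exact binomial (Clopper-Pearson) 95% interval on the split of UMIs between them. CPM values have exact Poisson intervals and shares of cells exact binomial ones. All intervals cover counting error only, not the difference between cultures or sorts. A count of 0 was set to 3 counts, which makes the ratio a bound. For each of 41 gene lists fixed before the data were examined, the median log2 ratio of members at 10 CPM or more in either library was computed. Its percentile among 10000 random lists of the same size matched on mean expression describes these libraries only. Intervals of list medians came from 1000 Poisson redraws. Of 697 genes in the lists, 692 had a symbol in the feature table. A list is called outside the random range where its median lies beyond the middle 95% of random lists.

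Comparisons were made between the 14 dpi libraries over neuron-like cells and over all kept cells, and between 14 dpi with supplements and 4 dpi over all kept cells. Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest log2 ratios among genes at 50 CPM or more in either library, leaving out Gm and Rik models, pseudogenes, ribosomal protein and mt- genes. From each list described it took the 2 highest and 2 lowest members at 20 CPM or more. Mnx1, Lhx3, Isl1, Neurog2, Trp53, Hras, Chat, Slc18a3, Mki67, Top2a, Col1a1 and Xist were always reported. Tubb3, v.EGFP, Gal and genes of the closing observations were chosen after their values were seen. Shares of cells with a UMI of a marker were compared after thinning every cell to 1000 UMIs, because depth per cell differed between libraries. This left out 31, 22 and 113 shallower cells in the order above.

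Alternatives fixed before the data were examined were all deposited barcodes, a stricter filter of 1000 genes and 10% mitochondrial UMIs, called doublets removed, median-of-ratios and TMM scaling, and totals without mitochondrial and ribosomal protein genes. Equal weight for each cell, thinned cells, other list minimums, other cell sets, Leiden resolutions 0.5 and 2, and clustering of each library alone were also fixed then. Added after seeing the data were the removal of the highest doublet scores, neuron-like cells without cluster 9, cells without cluster 14, and the naming rule tried first. The ratio step was tested on simulated data with 200 genes changed by known folds. Counts were drawn as Poisson sums per library, without single cells, which is the counting model of the intervals. Coverage near 95% therefore follows from the simulation and does not speak to spread between cells. For the comparison of neuron-like cells, 6495 genes were used, the median size of 2-fold changes came out at 0.99 on the log2 scale and that of 4-fold changes at 2.00. The intervals held the true value for 95% of the genes of each size. For the comparison of 4 and 14 dpi, 6405 genes were used and the intervals held it for 96% of genes changed 2-fold and 93% of those changed 4-fold. Over all kept cells of the 14 dpi libraries, 6502 genes were used and those shares were 98% and 96%. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and scikit-learn 1.9.0.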

Results

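The data are UMI counts of single cells from 3 libraries, each the only library of its group. After filtering, 2314 cells were kept from the 14 dpi library with supplements, 3716 from the 14 dpi library without supplements and 4492 from the 4 dpi library. The deposited totals were 37112015, 46150432 and 12290301 UMIs. Median depth per kept cell was 14380.5, 10664 and 2312.5 UMIs, with 4006.5, 3385 and 1201.5 genes. Depth therefore differed far more between 4 and 14 dpi than between the 14 dpi libraries, and the 4 dpi library was also sorted and dissociated in another way. Ribosomal protein genes took 13.9% of UMIs with supplements, 19.8% without supplements and 20.9% at 4 dpi, and mitochondrially encoded genes took 6.07%, 4.86% and 3.70%. No group had a second library, so no difference below has a replicate check.

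The reporter behind the Hb9::GFP gate was higher in both 14 dpi libraries than at 4 dpi, where stage and gate differ together. The reporter transcript v.EGFP stood at 2445 CPM with supplements (interval 2429 to 2461), 1911 CPM without supplements (1899 to 1924) and 182 CPM at 4 dpi (174 to 189). Mnx1, the motor neuron transcription factor whose regulatory sequence drives the reporter, was low in every library. It had 12.0 CPM with supplements, 21.4 CPM without supplements and 0.574 CPM at 4 dpi, the last from 7 UMIs. The proneural factor Neurog2 stood at 154, 109 and 297 CPM in the same order. The LIM-domain factors of the cassette stood at 92.9, 58.4 and 114 CPM for Lhx3 and at 88.7, 64.9 and 92.5 CPM for Isl1. Mouse Hras had 174, 121 and 120 CPM and Trp53, the gene of p53, had 115, 96.0 and 222 CPM. For these 5 genes the counts do not separate introduced from endogenous transcripts. Choline acetyltransferase, Chat, which makes acetylcholine, had 1.96 and 4.03 CPM at 14 dpi with and without supplements and 0 UMIs at 4 dpi. The vesicular acetylcholine transporter Slc18a3 had 16.1, 13.4 and 0.328 CPM.

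**Figure D1:**
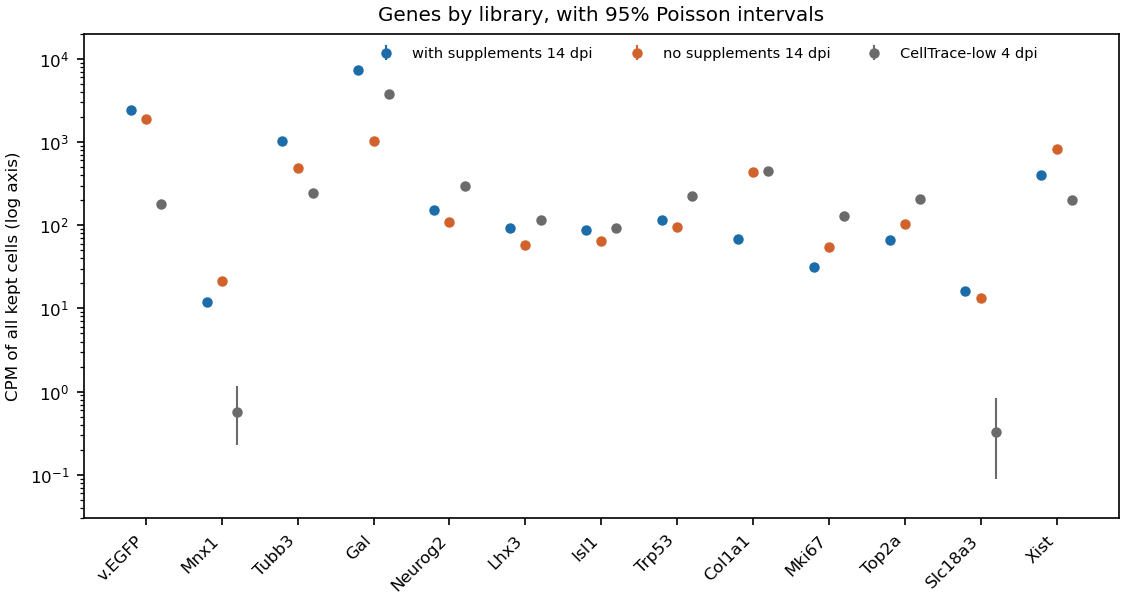
CPM over all kept cells on a log axis for genes followed in every library, 1 point per library with its 95% exact Poisson interval, which covers counting error only and is mostly narrower than the point. v.EGFP, Mnx1, Tubb3 and Slc18a3 were higher in both 14 dpi libraries than at 4 dpi, while Mki67 and Top2a were highest at 4 dpi and Col1a1 was lowest with supplements at 14 dpi.

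The first question was how many of the sorted cells resembled neurons. Neuron-like clusters held 1235 of 2314 cells with supplements, 53.4% (51.3 to 55.4), and 1934 of 3716 cells without supplements, 52.0% (50.4 to 53.7). At 4 dpi they held 10 of 4492 cells, 0.223% (0.107 to 0.409). Fibroblast-like clusters held 2.94% of cells with supplements (2.29 to 3.71), 19.8% without supplements (18.5 to 21.1) and 35.0% at 4 dpi (33.6 to 36.4). The 14 dpi cells had passed the Hb9::GFP gate and the 4 dpi cells the low CellTrace gate, and both gates can set these shares.

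The neuron-like cells of the 14 dpi libraries came from different clusters. With supplements, 1195 of them were in cluster 2, and without supplements 964 were in cluster 7 and 898 in cluster 9. Each of these clusters came mostly from 1 library and may be that library rather than a cell type. Cluster 9 had no neuron marker among its top 10 genes and passed the naming rule on the level of neuron against fibroblast markers, with a score of 2.30 against 3.07 for cluster 2 and 3.12 for cluster 7. The thresholds, set after seeing the data, left other clusters unnamed. Cluster 0, with a score of 0.66 and 16 of the 18 neuron and 17 of the 20 fibroblast markers detected, held 29.9% of cells with supplements, 0.323% without and 0.401% at 4 dpi. Its mean log2 of CPM plus 10, relative to 10, was 4.37 over neuron markers, against 4.55 in cluster 9. Over fibroblast markers it was 3.72 against 2.25. Stmn2 and Tubb3 stood higher in cluster 0, at 148 against 98.8 and 771 against 659 CPM, and v.EGFP lower, at 2294 against 3590 CPM. Cluster 8, at -0.48, held 17.1% of cells without supplements, 0.303% with supplements and none at 4 dpi. Cluster 11, at 1.01, held 3.59%, 1.21% and 5.81% with supplements, without supplements and at 4 dpi. Cluster 12, at -0.11, held 13.8% of the 4 dpi cells, 0.173% of those with supplements and 0.188% of those without. Cluster 5, at 1.99, held 1.21% of cells with supplements only, and cluster 6, a shallow cluster with a score of 2.40 that was left unnamed for its low UMIs, held 1.04% with and 0.942% without supplements. Cycling cells lay in cluster 1, with 6.53% of cells with supplements and 7.86% without, and in cluster 3, with 28.7% of the 4 dpi cells. Cluster 10, at -1.53, held 15.8% of the 4 dpi cells.

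The size of the gap between the 14 dpi neuron-like shares depended on the naming rule and the clustering. The share with supplements was the higher one in 8 of 9 settings, the main one included, by 1.33 to 30.7 points. These settings reuse the cells of the same libraries and are not independent. The exception was the removal of the highest doublet scores, at 52.2% against 52.4%, and the main gap of 1.33 points also has overlapping intervals. The naming rule tried first gave 52.6% with supplements and 27.9% without, since it left out cluster 9. Leiden resolution 0.5 gave 84.5% and 53.8%, and all deposited barcodes gave 59.8% and 34.0%.

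**Figure D2:**
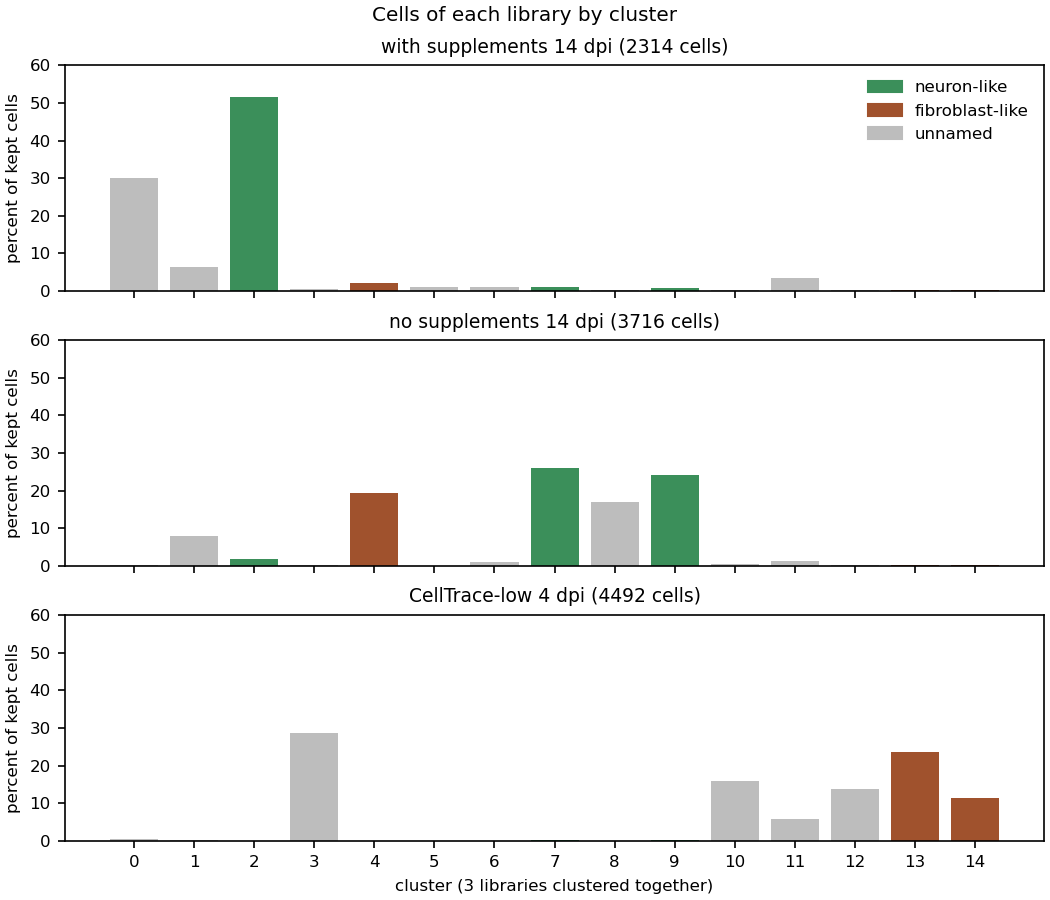
Percent of the kept cells of each library in each of 15 clusters of the 3 libraries together, 1 panel per library with its number of cells, bars coloured by the class given to the cluster. Cluster 2 held 51.6% of the cells with supplements, and clusters 7 and 9 held 25.9% and 24.2% of the cells without supplements.

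Marker shares needed no clusters. With every cell thinned to 1000 UMIs, Tubb3, a neuronal tubulin, was detected in 48.3% of cells with supplements (46.2 to 50.3), 28.5% without supplements (27.1 to 30.0) and 16.1% at 4 dpi (15 to 17.2). In fibroblast-like cells the thinned shares were 1 of 68 cells (1.47%, below the 4.41% that 3 cells make), 15 of 732 (2.05%) and 83 of 1514 (5.48%). Tubb3 and Stmn2 are among the neuron markers used for naming, so low levels in fibroblast-like cells are partly fixed by the naming and are no independent background. Before thinning, the shares in all kept cells were 85.0%, 64.1% and 30.7%, at median depths of 14380.5, 10664 and 2312.5 UMIs, and those in fibroblast-like cells were 33.8%, 13.5% and 13.7%, at 10938, 9125.5 and 1873 UMIs. Stmn2, a growth-associated regulator of microtubules, was detected after thinning in 34.8% of cells with supplements, 12.4% without and 0.617% at 4 dpi, against 3 of 68 (4.41%), 6 of 732 (0.820%) and 3 of 1514 (0.198%) fibroblast-like cells. S and G2/M genes together took 0.125% of UMIs with supplements (0.123 to 0.126), 0.141% without (0.140 to 0.142) and 0.362% at 4 dpi (0.359 to 0.366). Higher division is what the low CellTrace gate selects.

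The comparison of the 14 dpi libraries over neuron-like cells sets side by side the transcriptomes of the cells called neuron-like in each. Without supplements, genes of glycolysis and of the response to low oxygen were higher in these cells, with a list median log2 ratio of 1.77 (no supplements over with supplements, counting interval 1.72 to 1.80). Summed over these cells, genes of the integrated stress response and of axon injury were lower, with medians of -0.58 and -0.44. The comparison rests on 1934 cells without and 1235 cells with supplements, with 24537023 and 20440957 UMIs. Of those without supplements, 898 were of cluster 9, and cluster 0 was left out, so both sides need not be equally converted.

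All 23 measured members of the glycolysis and hypoxia list were higher without supplements, 21 of them at least 2-fold, and the median lay above all of 10000 random lists (percentile 100). Adm, the vasodilator peptide adrenomedullin, stood at 56.9 against 3.38 CPM (log2 ratio 4.08, interval 3.73 to 4.45). The glycolytic aldolase Aldoc stood at 32.4 against 3.03 CPM (log2 3.42). The smallest differences were those of Slc2a1, the widely expressed glucose transporter, at 71.7 against 37.2 CPM (0.95), and of Egln3, an oxygen-sensing hydroxylase, at 65.2 against 34.0 CPM (0.94). Over all kept cells Egln3 had a log2 ratio of -0.02.

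Several of the 12 genes with the highest ratios have related roles. Slc16a3, which exports lactate, stood at 57.3 against 6.41 CPM (log2 3.16), Slc2a3, the neuronal glucose transporter, at 56.1 against 6.80 CPM (3.04), and Bnip3, a receptor for the removal of mitochondria, at 516 against 62.9 CPM (3.04). Ndufa4l2, a mitochondrial protein induced by low oxygen, stood at 58.5 against 7.88 CPM (2.89, but 1.02 without cluster 9). The largest ratio was that of Krtdap, a secreted peptide of differentiating keratinocytes, at 83.3 against 0.832 CPM (6.65, interval 5.96 to 7.43, but 3.78 without cluster 9). Fxyd7, a regulator of the sodium pump in brain, followed at 53.1 against 2.98 CPM (4.15). The neuropeptide gene Cck stood at 809 against 84.7 CPM (3.26) and the metallothionein Mt3 at 63.9 against 7.34 CPM (3.12). Mgp and Bgn, both of extracellular matrix, and the secreted protein gene Olfm2 had log2 ratios of 2.68, 2.53 and 2.48. Mgp had a log2 ratio of -1.18 with neuron-like clusters taken at resolution 0.5. It is also among the top 10 genes of fibroblast-like cluster 4, which held 19.4% of cells without and 2.20% with supplements. RNA carried over from such cells was neither corrected for nor tested.

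The 12 lowest ratios included secreted neuropeptides. Vip stood at 0.774 CPM without supplements against 87.5 CPM with them (log2 -6.82, interval -7.56 to -6.17). Cartpt stood at 35.1 against 516 CPM (-3.88) and neurotensin, Nts, at 41.0 against 524 CPM (-3.67). Tph1, an enzyme of serotonin synthesis, stood at 7.78 against 107 CPM (-3.78). The granzyme genes Gzme and Gzmd, best known as proteases of cytotoxic lymphocytes, had log2 ratios of -5.40 (interval -5.72 to -5.09) and -4.57. Gria4, a subunit of AMPA-type glutamate receptors, stood at 3.67 against 67.5 CPM (-4.20). The netrin receptor Unc5d and the prokineticin receptor Prokr1 had log2 ratios of -3.28 and -3.47, Pcp4l1 had -3.38, and Pmp22, a protein of peripheral myelin, had -3.11. Many of the highest and lowest genes, among them Krtdap, Cck, Bnip3, Fxyd7, Cartpt, Nts, Gzmd, Gzme and Unc5d, also lead clusters 2, 7 or 9, so clusters and ratios are not independent. Each of these genes had the same sign over all kept cells, where no cluster was used. Those sums include the neuron-like cells, which with supplements held 10548 of 12207 Cartpt UMIs and 10701 of 12693 Nts UMIs. The like sign is therefore partly fixed in advance and is no separate check.

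The integrated stress response list had 16 of 19 members lower without supplements, and its median of -0.58 (counting interval -0.67 to -0.53) lay at percentile 0.0 of random lists. Sdf2l1, a cofactor of protein folding in the endoplasmic reticulum, stood at 30.4 against 68.3 CPM (log2 -1.17), and Mthfd2, a mitochondrial enzyme of folate metabolism, at 145 against 285 CPM (-0.98). Ddit4, an inhibitor of mTOR signalling that is induced by stress and by low oxygen, went the other way at 32.7 against 20.8 CPM (0.65). Nupr1 had 139 against 132 CPM (0.08), a sign that changed under other settings. The axon injury and apoptosis list had a median of -0.44 (-0.50 to -0.40), percentile 0.09, with 5 of 17 members at least 2-fold lower. Sprr1a, which injured neurons induce, stood at 1.67 against 112 CPM (-6.07, interval -6.55 to -5.63, but -5.36 without cluster 9), and galanin, Gal, at 1636 against 9806 CPM (-2.58). Hrk, a promoter of neuronal apoptosis, was higher at 91.6 against 37.2 CPM (1.30), and Jun had 405 against 344 CPM (0.23). Within clusters 2, 7 and 9, where the smaller side held 72, 23 and 17 cells, the injury median was 0.03, 0.01 and -0.09 and the stress response median -0.01, -0.60 and -1.62. Within the cycling cells of cluster 1, with 292 and 151 cells, these medians were -0.61 and -0.16. Gal stood at 2463 CPM without against 9930 CPM with supplements in cluster 2 and at 2081 against 7097 CPM in cluster 7, but at 1072 against 307 CPM in cluster 9. Cells were placed in these clusters by expression, Sprr1a being among the top 10 genes of cluster 2, and few lie on the smaller side, so these values do not settle whether the difference lies within or between clusters.

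The pan-neuronal list had a median of -0.16 over 20 members, at percentile 17.1, and the synaptic vesicle list 0.02 over 21 members, at percentile 67.2, both within the random range. The cells had been chosen by a minimum level of neuron markers, so these medians do not show how neuronal the libraries were as a whole. Members moved both ways. Stmn2 stood at 461 against 1409 CPM (log2 -1.61, but -0.90 without cluster 9), the growth cone protein gene Gap43 at 1169 against 2633 CPM (-1.17) and Tubb3 at 811 against 1357 CPM (-0.74). The heavy neurofilament gene Nefh had a log2 ratio of 1.79 (interval 1.52 to 2.07) and the neuronal splicing factor Rbfox3 stood at 42.2 against 13.6 CPM (1.63). Of genes of secretory vesicles, Scg2 and Syt4 had log2 ratios of -2.01 and -1.86, and Chgb and Sv2a 1.27 and 1.21.

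The motor neuron list had a median of 0.20 at percentile 90.5, within the random range, with 5 of 13 members at least 2-fold higher and 1 at least 2-fold lower without supplements. Ecel1, a protease needed for motor axon branching, stood at 193 against 49.6 CPM (log2 1.96) and Mnx1 at 34.8 against 13.3 CPM (1.39, interval 1.19 to 1.59). Chat stood at 6.68 against 2.59 CPM (1.37, interval 0.91 to 1.84), while Slc18a3 had 22.2 against 23.0 CPM (-0.05, -0.23 to 0.13), and a ratio of 0.31 without cluster 9. Lhx3 and Isl1 had log2 ratios of -0.45 and -0.45, Neurog2 -0.43, Hras -0.50 and Trp53 -0.27. The proliferation genes Mki67 and Top2a were under 10 CPM on both sides, with ratios of -0.36 and -0.04 whose intervals include 0. v.EGFP stood at 2684 against 2390 CPM (0.17), but at -0.36 over all kept cells and -0.27 without cluster 9.

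TGF-beta response genes had a median of 0.11 over 11 members, at percentile 68.2. The feedback inhibitors Pmepa1 and Skil, both induced by TGF-beta, stood at 96.5 against 26.5 CPM (log2 1.86) and 89.0 against 27.6 CPM (1.69). Tgfb1i1 and Id1 had ratios of -1.53 and -0.49. The fibroblast matrix list had a median of -0.18 over 21 members, at percentile 9.80, with 4 members at least 2-fold higher and 6 at least 2-fold lower. Collagen gene Col1a1 stood at 34.4 against 7.88 CPM (2.13), but at -0.11 with resolution 0.5. Col1a1 is among the top 10 genes of fibroblast-like cluster 4, and RNA carried over from such cells was not tested. Timp1, an inhibitor of matrix proteases, stood at 17.3 against 91.3 CPM (-2.40), but at 0.54 over all kept cells, and Postn, a matrix protein, at 53.8 against 223 CPM (-2.05). Xist, the X-inactivation transcript of female cells, stood at 999 against 408 CPM (1.29). Over all kept cells, UMIs of Xist without Y-linked genes were found in 50.2% of cells without and 36.7% with supplements, counted without thinning, while 4 Y-linked genes together stood at 101 and 100 CPM. Ddx3y stood at 47.5 against 37.3 CPM and Eif2s3y at 33.0 against 42.4 CPM. Supplements and culture cannot be told apart with 1 culture of each kind.

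Over all kept cells of the same libraries, which include fibroblast-like and cycling cells, the matrix and TGF-beta lists were higher without supplements. The TGF-beta response list had a median of 0.75 (counting interval 0.67 to 0.84) and the matrix list 0.53 (0.49 to 0.57), both at percentile 100. Glycolysis and hypoxia genes had a median of 1.63 at percentile 100, with 21 of 23 members at least 2-fold higher. The motor neuron list was at 0.29, percentile 98.4, above the random range of -0.33 to 0.26, while the pan-neuronal list was at -0.36, percentile 1.02, the stress response list at -0.53 and the axon injury list at -0.57, both at percentile 0.01. These values mix changes within cells with the larger share of fibroblast-like cells without supplements. Within clusters the TGF-beta median was 1.02 in fibroblast-like cluster 4, with 720 and 51 cells, and 1.14 in cycling cluster 1. In these, 13 of 18 and 12 of 15 members were above 0, 9 and 8 of them at least 2-fold. The median was -0.16, -0.19 and -0.53 in neuron-like clusters 2, 7 and 9, with 72, 23 and 17 cells on the smaller side. There members moved both ways, with 5 of 11, 6 of 13 and 5 of 14 above 0, of which 4, 5 and 4 at least 2-fold.

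Col1a1 stood at 432 CPM without supplements and 68.1 CPM with them (log2 2.66, interval 2.60 to 2.72), and Lox, which crosslinks collagen, had a log2 ratio of 2.90 (2.76 to 3.03). Lum, a matrix proteoglycan, went the other way at 55.5 and 125 CPM (-1.17). Pmepa1 stood at 108 and 25.1 CPM (2.11). Lcn2, an iron-scavenging secreted protein, Mmp3, a matrix protease, and Ero1a, an oxidase of protein folding induced by low oxygen, had log2 ratios of 3.70, 3.02 and 2.74. Calb1, a calcium buffer of many neurons, stood at 24.4 and 246 CPM (-3.33), Igf1, a growth factor, at 5.50 and 54.7 CPM (-3.32), and Gal at 1020 and 7261 CPM (-2.83). Mki67 and Top2a had ratios of 0.76 and 0.61, and the G2 and M phase list a median of 0.34 at percentile 99.5.

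The comparison of 14 dpi with supplements against 4 dpi sets the end of conversion beside an intermediate stage. Neuronal genes were much higher at 14 dpi, and genes of proliferation, fibroblast matrix, contraction and interferon response were higher at 4 dpi. The median log2 ratio (14 dpi over 4 dpi) was 2.81 for pan-neuronal genes (counting interval 2.76 to 2.89), 3.52 for synaptic vesicle genes (2.90 to 3.83), -1.83 for G2 and M phase genes (-1.90 to -1.74) and -1.99 for interferon genes (-2.07 to -1.91). The libraries differ in age, in the sort gate, in dissociation and in depth at once, with 36782509 UMIs at 14 dpi and 12202809 at 4 dpi. Median-of-ratios and TMM scaling would move the median of all genes by 0.15 and 0.13, which is small beside these medians.

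All 18 measured pan-neuronal members were at least 2-fold higher at 14 dpi, as were 18 of 19 synaptic members, and both medians lay at percentile 100. Stmn2 stood at 842 against 5.74 CPM (log2 7.20, interval 6.86 to 7.56) and its relatives Stmn3 and Stmn4 had ratios of 7.21 and 9.19, the latter at 191 against 0.328 CPM, from 4 UMIs at 4 dpi. Tubb3 stood at 1039 against 241 CPM (2.11). The smallest pan-neuronal differences were those of the neurofilament gene Nefl, at 2136 against 664 CPM (1.68), and the adhesion molecule gene Ncam1, at 462 against 138 CPM (1.74). Syt4, a vesicle protein, stood at 172 against 0.410 CPM (8.71), and Cplx1, which controls vesicle fusion, had 1839 UMIs against 1 at 4 dpi (9.25, interval 6.77 to 14.56). Sv2b had a ratio of 0.22, and of -0.90 with the library without supplements in place of that with supplements. Pcsk1n, of prohormone processing, the G protein subunit gene Gng3 and the synaptic adhesion gene Nrxn3 had ratios of 7.79, 7.04 and 6.31.

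Neuropeptide genes were among the 12 highest. Cartpt had 12207 UMIs at 14 dpi and 1 UMI at 4 dpi (log2 11.98, interval 9.51 to 17.29) and Nts stood at 345 against 2.95 CPM (6.87). Gzmd had a ratio of 8.84 from 3 UMIs at 4 dpi (interval 7.29 to 11.12), and Gzme had 3475 UMIs against 9 (interval 6.07 to 8.13). Gal was abundant at both times, at 7261 against 3768 CPM (0.95), but its ratio was -1.89 with the library without supplements.

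The motor neuron list had a median of 1.15 at percentile 96.6, inside the random range, with 8 of 13 members at least 2-fold higher at 14 dpi. Ret, the receptor component for GDNF, had 2022 UMIs against 1 (log2 9.39, interval 6.91 to 14.69), Ecel1 a ratio of 5.08 and Mnx1 4.39 (3.33 to 5.71). Slc18a3 had a ratio of 5.62 (4.25 to 7.50). Chat stood 7.96-fold above the limit of 3 counts at 4 dpi, and the lower end of its counting interval was 6.31-fold. Slc5a7, the choline transporter, was lower at 14 dpi at 19.6 against 39.1 CPM (log2 interval -1.17 to -0.83), and Agrn, which organises the neuromuscular synapse, had -0.30. The Agrn ratio was 0.10 with thinned cells and 0.85 with the library without supplements. Neurog2 had -0.94, Lhx3 -0.30, Isl1 -0.06 with an interval of -0.16 to 0.04, Hras 0.53 and Trp53 -0.96. v.EGFP had 3.75, beside the Hb9::GFP gate at 14 dpi.

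Of G2 and M phase genes, 26 of 26 were at least 2-fold lower at 14 dpi, and of S phase genes 17 of 24, with a median of -1.34. Both medians lay at percentile 0.0. The proliferation genes Mki67 and Top2a stood at 31.9 against 130 CPM (log2 -2.03) and 67.3 against 208 CPM (-1.62). The kinetochore motor Cenpe, the cyclin Ccnb2 and the ribonucleotide reductase subunit Rrm2 had ratios of -2.43, -2.35 and -2.32, and the replication helicase subunit Mcm6 had -2.12. The members that moved least were Cdk1 at -1.34 and Nusap1 at -1.39 in the first list, and Slbp at -0.45 and Hells at -0.47 in the second. The low CellTrace gate at 4 dpi stands beside each of these values.

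Fibroblast matrix genes were lower at 14 dpi, with a median of -1.13, all 22 members below 0 and 14 at least 2-fold lower. Col1a1 stood at 68.1 against 450 CPM (log2 -2.72) and Fbln2, a matrix glycoprotein, at 11.7 against 124 CPM (-3.41), while Mmp2 and Timp1 had -0.46 and -0.54. With the library without supplements the Timp1 ratio was 0.01. Contractile genes had a median of -1.64, with 9 of 12 at least 2-fold lower. Smooth muscle actin, Acta2, stood at 6.96 against 93.3 CPM (-3.75), Tagln at 7.23 against 42.7 CPM (-2.56), and Cnn2 and Vcl had -0.92 and -0.68. Of p53 targets, 8 of 19 were at least 2-fold lower and none at least 2-fold higher, with a median of -0.87. Fas, a death receptor, had -2.37 and Ccng1, a cyclin, -2.05, while Rrm2b and Bbc3 had 0.61 and 0.46. The medians of these 3 lists lay at percentile 0.0.

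Interferon response genes had 16 of 20 members at least 2-fold higher at 4 dpi, at percentile 0.0. The chemokine gene Cxcl10 stood at 25.6 CPM at 14 dpi against 797 CPM at 4 dpi (log2 -4.96, interval -5.06 to -4.86) and Ifit3, an antiviral protein gene, at 14.0 against 374 CPM (-4.74). Ifi27 went the other way at 202 against 113 CPM (0.84), and Ifi27l2a had -0.19, a sign that changed under 3 other settings. The lowest ratios of all genes at 50 CPM or more included the chemokines Ccl5 (-5.95) and Ccl7 (-4.63), the guanylate-binding protein Gbp2 (-4.74), Ifit3b (-4.78), Phf11d (-4.47) and Parp14 (-3.91). Tspo, a protein of the outer mitochondrial membrane, and Itih5, a hyaluronan-binding protein, had -3.41 and -3.40. Xist stood at 398 against 203 CPM (0.97), and Y-linked genes together at 100 against 86.1 CPM. Without thinning, UMIs of neither kind were found in 13.4% of cells at 14 dpi and 56.2% at the lower depth of 4 dpi, so shares of cells of each sex are not compared here. Of the sign changes named for this comparison, those with the library without supplements replace 1 side by another library.

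**Figure D3:**
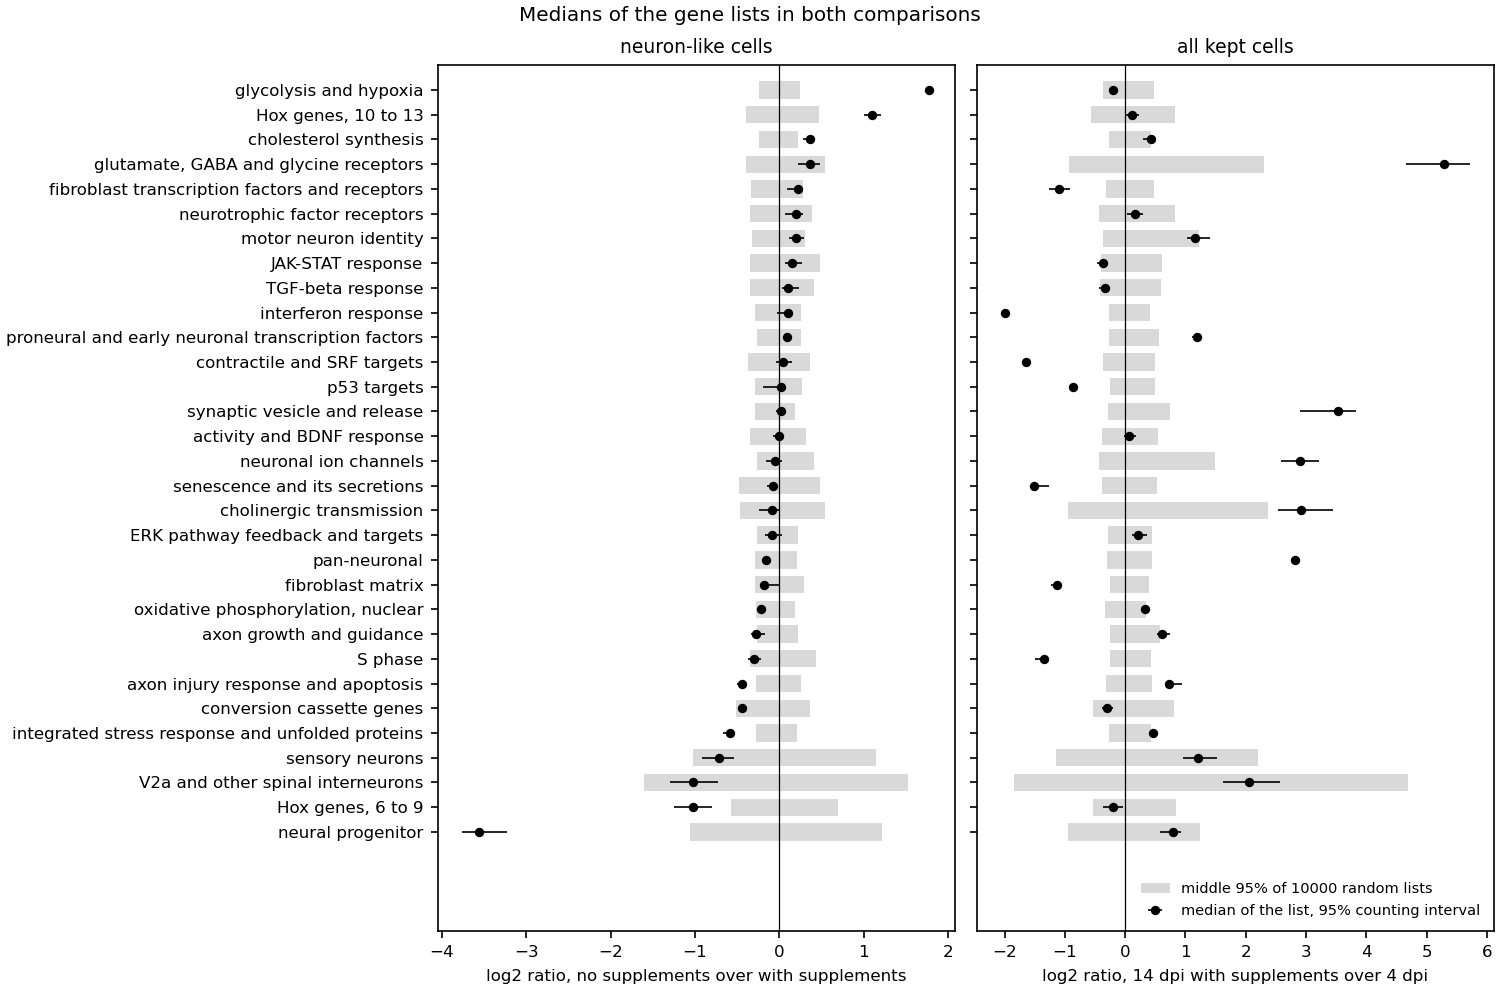
Median log2 ratio of each gene list measured in both comparisons, no supplements over with supplements in neuron-like cells on the left and 14 dpi with supplements over 4 dpi in all kept cells on the right, each point with its 95% counting interval and each grey bar showing the middle 95% of 10000 random matched lists. Glycolysis and hypoxia genes lie at 1.77 on the left and -0.20 on the right, and pan-neuronal genes at -0.16 and 2.81.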

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

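The removals of clusters 9 and 14 and of high doublet scores, and the naming rule tried first, were chosen after the data were seen. All other alternatives were fixed before. No replicate could be left out, and no paired analysis was possible because each group has 1 library, so that the replicate number the labels share pairs nothing. Among lists outside the random range in the neuron-like comparison, 114 of 115 values of 8 lists kept their sign over up to 15 alternatives, as did 771 of 780 values of the 60 named genes whose counting interval excludes 0. Between 4 and 14 dpi these were 246 of 248 values of 18 lists and 772 of 780 values of 65 genes. The median-of-ratios and TMM factors of the neuron-like comparison were only -0.0145 and -0.0082 on the log2 scale, so such settings could change few signs. All alternatives also use the same libraries, so these tallies say nothing of other cultures. Of named genes whose interval includes 0, Slc18a3, Mki67 and Top2a changed sign in 17 of 39 values and Isl1, between 4 and 14 dpi, in 2 of 12. Low depth at 4 dpi limits what can be said of genes near 0.246 CPM there, the level of 3 UMIs. Except where said, the cause of a shift was not tested.

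The share of neuron-like cells moved with the choices. It was higher with than without supplements in 8 of 9 settings, by 1.33 to 30.7 points, and the removal of the highest doublet scores, with a near tie, was the exception. The settings reuse the same libraries, so their number is no measure of support. Removing only the 3, 1 and 1 called doublets moved the gap from 1.33 to 7.03 points, so the clusters themselves are unstable. With supplements the share of cells in neuron-like clusters was 84.5% at resolution 0.5, 68.5% at resolution 2, 63.0% with each library clustered alone, 59.8% with all deposited barcodes, 56.8% with the stricter filter and 56.6% with called doublets removed. Without supplements these values were 53.8%, 49.4%, 36.4%, 34.0%, 36.3% and 49.5%. At 4 dpi they were 0.512%, 0.579%, 0%, 0.348%, 0.327% and 0.134%. The naming rule tried first gave 52.6%, 27.9% and 0.134% in the 3 libraries, and the removal of the highest doublet scores 52.2%, 52.4% and 0.211%. Cluster 9 alone holds 24.2% of cells without supplements and cluster 0 holds 29.9% of cells with supplements, and whether each counts as neuron-like moves the share. Under the rule tried first, the neuron-like comparison is the one without cluster 9 given below.

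The share of cells with a UMI of Tubb3 was 63.8% with supplements, 41.6% without and 29.1% at 4 dpi with cells thinned to 2000 UMIs, and 85.0%, 64.1% and 30.7% without thinning, as deeper cells show more. The share of UMIs from S and G2/M genes was 0.133%, 0.143% and 0.400% with the stricter filter and 0.114%, 0.121% and 0.317% with equal weight per cell.

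In neuron-like cells, no supplements against with supplements, the median of glycolysis and hypoxia was 1.63 with all deposited barcodes, 1.84 without mt-, Rpl and Rps genes in the total, 1.86 with equal weight per cell, 1.63 over all kept cells, 1.72 at resolution 2, 1.68 at resolution 0.5 and 1.56 without cluster 9. Axon growth and guidance, at -0.28, was 0.0544 without cluster 9. Nupr1 was -5.06e-05 with equal weight, -0.17 with thinned cells and -0.19 without cluster 9. Over all kept cells Egln3 was -0.0157, Timp1 0.54 and v.EGFP -0.36, and v.EGFP was -0.27 without cluster 9. At resolution 0.5 Mgp was -1.18 and Col1a1 -0.11. Without cluster 9, 14 of the 60 named genes whose interval excludes 0 moved by over 1.5-fold, 11 of them toward 0. Krtdap went from 6.65 to 3.78, Ndufa4l2 from 2.89 to 1.02 and Stmn2 from -1.61 to -0.90, and, away from 0, Vip from -6.82 to -8.62. Sprr1a, Gzme, Gzmd, Gria4, Nts and Unc5d came to -5.36, -4.58, -3.72, -3.47, -2.92 and -2.63, and Adm and Col1a1 to 3.36 and 1.39. Fxyd7 and Nefh also moved away from 0, to 4.92 and 2.40. Slc18a3 was 0.31.

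In all cells, 4 dpi against 14 dpi with supplements, the pan-neuronal median was 2.67 with median-of-ratios and 2.69 with TMM scaling, 3.09 without mt-, Rpl and Rps genes in the total, 2.69 with equal weight and 3.003 with thinned cells. It was 3.38 with no list minimum, 2.46 with a minimum of 50 CPM, 3.71 with neuron-like cells alone at 14 dpi and 2.91 with the library without supplements. The value with neuron-like cells alone is raised by construction, since those cells were named by neuron markers that the list shares. The G2 and M phase median was -1.98 and -1.96 with these scalings, -1.92 without mt-, Rpl and Rps genes and -1.68 with the minimum of 50 CPM. It was -4.62 with neuron-like cells alone, which leaves the cycling clusters out by construction, -1.47 with the library without supplements and -1.93 without cluster 14. The integrated stress response and the axon injury response and apoptosis lists had main medians of 0.46 and 0.72, at percentiles 98.5 and 99.97. With the library without supplements, these medians were -0.0459 and -0.0532, and Sv2b was -0.90, Agrn 0.85, Timp1 0.00586, Ifi27l2a 1.22 and Gal -1.89. Agrn was 0.10 with thinned cells. Ifi27l2a was 0.47 with the stricter filter and 0.25 without cluster 14.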

Other observations

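Tests of the explanations below were written with their expected outcomes before their results were computed, on patterns found in the same data. The removals of clusters 9 and 14 were added after the data were seen. The medians of cells with Xist only, of neuron-like cells by sex and of fibroblast-like over neuron-like cells were added after the other tests were seen.

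Members of the Hox clusters, which mark position along the body axis, differed between the 14 dpi libraries. Over neuron-like cells the list of Hox genes 6 to 9 had a median log2 ratio (no supplements over with supplements) of -1.02 (counting interval -1.25 to -0.80, percentile 0.14), with 4 of 7 members at least 2-fold lower, but 3 above 0 and 1 of these, Hoxa9, at least 2-fold higher at 44.4 against 21.0 CPM. Of the lower members, Hoxb9 stood at 19.8 against 48.3 CPM. The list of Hox genes 10 to 13 had a median of 1.10 (1.00 to 1.20, percentile 100), with 4 of 6 at least 2-fold higher and 1 below 0. Hoxa10 stood at 100.5 against 39.3 CPM, Hoxa11 at 38.1 against 11.1 CPM and Hoxd11 at 74.7 against 33.2 CPM. Over all kept cells the medians were -0.88 and 0.74. Cells that hold transcripts of the sex chromosomes differed in number as well, counted without thinning at median depths of 14380.5 UMIs with and 10664 without supplements. UMIs of Xist and of no Y-linked gene were found in 36.7% of cells with supplements (34.8 to 38.7) and 50.2% without (48.5 to 51.8), and UMIs of Y-linked genes without Xist in 43.9% and 33.3%. Both kinds were found in 6.01% and 5.89% of cells. Over all kept cells Xist stood at 398 CPM with and 828 CPM without supplements, but the Y-linked genes together at 100 and 101 CPM. Whether the mix of female and male cells differed is therefore not settled. Other lists over neuron-like cells included cholesterol synthesis, with a median of 0.36 at percentile 99.9, and neural progenitor genes, with -3.56 over 3 measured members, of which the stem cell genes Sox2 and Nes stood at 3.55 against 43.2 CPM and 3.42 against 40.4 CPM.

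At 4 dpi, cluster 12 held 618 cells with high early neuronal transcripts but little Stmn2 beside the 14 dpi cells. In these cells Neurog2 stood at 530 CPM, which may include the introduced gene. Hes6, a factor of early neurogenesis, stood at 377, Tubb3 at 763, v.EGFP at 824 and Stmn2 at 23.8 CPM. Stmn2 had 5.74 CPM over all 4 dpi cells and 842 CPM at 14 dpi with supplements. At 14 dpi, 28 cells with supplements formed cluster 5, with 15119 CPM of v.EGFP and 1097 CPM of peripherin, Prph, an intermediate filament of motor and peripheral neurons. Slc18a3 and Chat had 2 and 0 UMIs in them, too few to tell their level from that of neuron-like cells. Its top genes were led by Fabp4, a fatty acid carrier. Between 14 dpi with supplements and 4 dpi, the list of senescence and its secretions had a median of -1.50 at percentile 0.0, with 8 of 13 members at least 2-fold lower at 14 dpi, and proneural and early neuronal transcription factors had 1.19 at percentile 100.

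Higher glycolysis and hypoxia genes without supplements would, if the cells of cluster 9 carried the pattern alone, have a median in the random range without them, but it was 1.56 over the remaining neuron-like cells. If the mix of female and male embryos carried it, the median would be small among cells of like sex, but over all kept cells it was 1.83 among cells with Xist, 1.81 without those that also hold Y-linked UMIs, and 1.40 among cells with Y-linked UMIs and no Xist, and over neuron-like cells it was 1.88 with Xist only and 1.60 with Y-linked UMIs only. If the sort had only taken other classes of cells, the median within the cycling cells of cluster 1 would be small, but it was 1.56 over 292 and 151 cells. In clusters with fewer cells on a side it ran from 0.36 in cluster 0, with 12 cells without supplements, to 1.47 in cluster 4. In neuron-like clusters 2, 7 and 9, with 72, 23 and 17 cells on the smaller side, it was 0.95, 1.27 and 1.34. These lie below the 1.77 over all neuron-like cells, so part of that value may lie between clusters. Cluster 1 is itself mixed, with Col1a1 at 538 against 102 CPM and Tubb3 at 115 against 439 CPM without and with supplements. Fibroblast-like over neuron-like cells had medians of -0.13 with and -0.54 without supplements, so more fibroblast-like cells would lower the list. Other mixes were not examined, such as cells like those of unnamed cluster 8, with 635 cells without and 7 with supplements. Cluster 1 therefore cannot exclude a difference in which cells were sorted. A difference in which cells were sorted stays open. So does a difference between cultures, such as cell density or medium, which may accompany the supplements or not. The effect of the supplements themselves also stays open, untested with 1 culture of each kind.

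Higher interferon genes at 4 dpi were weighed in the same way. If the cells of cluster 14, where the list was highest at 18171 CPM, carried the pattern alone, the median would come close to 0 without them, but it was -1.81. If immune cells carried it, the median would come close to 0 without cells that hold a UMI of an immune marker, but it was -1.97 over 2126 cells at 14 dpi and 4456 at 4 dpi, and the most abundant of these markers at 4 dpi, Fcer1g and Lyz2, stood at 5.57 and 5.00 CPM. In other clusters with over 100 cells at 4 dpi the list stood at 3517 to 12234 CPM, against 2215 CPM over all cells at 14 dpi with supplements. Stage of conversion, the response to introduced genes, the low CellTrace gate and trypsin dissociation stay open, untested because they come together in the design.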
